A study of Drosophila melanogaster with 2 samples.

How the data were processed

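Chromatin immunoprecipitation and sequencing was done on whole embryos of transgenic flies that carry a Snail-eGFP fusion, aged 0 to 24 h, in 2 biological replicates of 1 group. Per the labels' protocols, chromatin was sonicated to fragments of about 200 to 800 bp and precipitated with an antibody against GFP. The antibody field of the labels names sna, and the description names GFP. Samples of the control experiment that the labels name were not analysed here. The aligner and the peak caller are not given in the sources used here. Peak coordinates are on dm6, per the labels.

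The authors deposited peak lists in the narrowPeak layout at 2 levels. Ranked lists hold all candidate regions, and thresholded lists hold the peaks kept at an IDR of 0.01, a measure of how well the rank of a peak repeats. Each replicate has 1 list of each kind, called on that replicate alone. The other 4 lists cover the whole series: 1 pooled list, whose 4222 thresholded peaks are the main list here, and 1 list made from the pair of replicates, with 3755 thresholded peaks. A peak of the pooled list need not be in either replicate's own thresholded list. The signal of each peak is the authors' own enrichment value, and its scale is not given in the sources used here. The q value column is the authors' −log10 value, and the IDR columns are the authors' −log10 values as well. The score column and the per-replicate columns of the replicate-pair list are the authors' deposited score values, used as given. In that list the coordinates of the first column set were found in the replicate 1 candidate list for 67.3% of 96022 regions and in that of replicate 2 for 0%, and those of the second set in that of replicate 2 for 81.1% and in that of replicate 1 for 0%, so the first was taken as replicate 1 and the second as replicate 2. No file gives read counts, so depth is unknown, and the number of replicates limits the precision. Intervals on shares of peaks are 95% Wilson intervals and cover counting error only. Peaks and genes are not independent replicates, so their p-values describe these lists and not the spread between embryos.

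Peaks off the 6 main arms (1 in the main list) were left out. Some peaks of a list overlap each other: merging them leaves 3591 sites of the 4221 main peaks. Gene models were those of Ensembl release 115 and sequence that of the NCBI copy of the same Release 6 assembly, and no peak ended past the end of an arm. A summit was called promoter if within 500 bp of any annotated start site, and otherwise 5' UTR, coding exon, 3' UTR, noncoding exon, intron or intergenic, in this order. Overlap of replicates was 1 bp or more, set against 1000 shuffles within arms (one-sided), and the counts were the same with bedtools 2.31.1. Location was set against 1000 sets of random positions on the same arms, arm density against length with exact binomial tests, and signals against 100000 permutations. A gene counted as having a peak if a summit lay within its span extended by 5000 bp on each side. Lists were set against 10000 random lists matched on length in 20 bins. Of the 290 list entries, 10 were older symbols matched to current ones through the reference gene table, and all entries matched. Motifs were searched on both strands within 100 bp of the summit and in a window of the same width 1000 bp to a seeded side, with exact McNemar tests. Adjusted p-values are Benjamini-Hochberg within each family, with a threshold of 0.05.

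Groups, tests, gene lists, motifs and alternatives were fixed before the data were examined. Named in the text are the 15 peaks of highest signal, the first 10 in full; up to 4 members of each list with the strongest peak; the 17 genes sna, esg, wor, twi, sim, rho, sog, brk, ths, vnd, Mef2, tin, htl, zfh1, fog, shg and stg whatever their values; and the 10 coding genes with most summits. The names of other genes outside this rule (those nearest to a named peak, kune and the 3 left out of the protease list) were chosen after their values were seen. Other settings chosen beforehand were the replicate-pair list, the peaks above the median signal, each replicate's own list, other overlap rules, promoter widths, gene extensions, matching, windows, flanks and backgrounds. Merging overlapping peaks, splitting promoter from distal peaks and leaving 3 genes out of the protease list were added after seeing the data.

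The tests were tested on simulated data. Lists of 1000 peaks made with 50% shared peaks gave 50.2% overlap. Of 200 random gene lists of 50 genes 3.5% were called at 0.05 before adjustment. Of 200 lists of 50 genes with 40 bound 100% were. Many fixed lists were smaller, such as those of 8 Hox and 26 mesoderm genes, and the power for these was not measured. Lists of neighbouring genes that share a peak were not simulated. None (0) of 17 motifs was called at random summits, and CAGGTG planted in 20% of 4000 windows was recovered with a gain of 18.4 percentage points where 18.4 were due. The random summits lay anywhere on the arms, whereas most peak summits lay at promoters. The simulation thus does not show how the motif test behaves where summits and flanks differ in composition. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.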

Results

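Snail is a zinc-finger transcription factor that represses transcription in the presumptive mesoderm of the fly embryo and is needed for gastrulation. The series measured where a Snail-eGFP fusion protein, made from a transgene, lay on the genome of whole Drosophila melanogaster embryos collected over 0 to 24 h of development, by chromatin immunoprecipitation with an antibody against GFP and sequencing. There was 1 group of embryos with 2 biological replicates, so the comparisons that the design allows are between the replicates and, within a peak list, between peaks, genes and sequences. The files give peaks and no read counts, so the sequencing depth of each replicate is unknown. The main list, called on the pooled replicates and kept at an irreproducible discovery rate (IDR) of 0.01, held 4222 peaks with a median width of 516 bp, of which 4221 lay on the 6 main chromosome arms. Peak positions are on dm6 and were counted from 1. The signal value of a peak is the authors' own and its scale is unknown, so it is compared only within a list, and between the replicates only by correlation.

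The 2 replicates shared most of their strongest sites, above all at promoters, and differed most among weaker peaks. Replicate 1 had 2876 thresholded peaks and replicate 2 had 2225. Of the replicate 1 peaks, 62.2% (95% Wilson interval 60.5 to 64.0, 1790 peaks) overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks 82.1% (80.5 to 83.7, 1827 peaks) overlapped a replicate 1 peak. Shuffling the second list within chromosome arms gave 1.33% and 1.71% on average. None of 1000 shuffles reached either observed share (permutation p = 0.001, one-sided, the smallest they can give). The shuffles placed peaks anywhere on an arm, whereas 89.22% of replicate 1 peaks and 89.98% of replicate 2 peaks lay at a promoter. This test therefore cannot tell shared sites from a shared preference for promoters. No shuffle among promoters was run. Replicate 1 peaks that overlapped had a median signal of 108 against 63.2 for those that did not, and 93.7% against 81.8% of them lay at a promoter. For replicate 2 the medians were 80.4 and 53.7, and the promoter shares 93.3% and 74.6%. Almost every thresholded peak overlapped some region of the other replicate's candidate list, which also holds its thresholded peaks: 98.4% for replicate 1 and 99.1% for replicate 2. These lists are long enough that shuffling them gave 46.9% and 25.9%.

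Across the 79210 pairs of candidate regions that the replicate-pair list matches, the signals of the 2 replicates had a Spearman rho of 0.31 and a Pearson r of 0.46 on the log10 scale (permutation p = 1e-05 for both, two-sided, the smallest that 100000 resamples can give). This correlation is across regions, which are not independent replicates. Among the 4000 pairs in the main list rho was 0.66 and r was 0.61, and among the 32844 pairs whose summits lay within 100 bp they were 0.46 and 0.61. The pooled list of 4222 peaks was 1.12 times as long as the list of 3755 peaks called from the replicate pair, and the replicate 1 list was 1.29 times as long as the replicate 2 list. The candidate lists differed more, with 103224 regions in replicate 2 and 46960 in replicate 1.

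The peaks lay mainly at transcription start sites. No control sample was used here, so binding of the tagged protein could not be told from background signal. Of the 4221 summits, 3543 (83.9%, 95% Wilson interval 82.8 to 85.0) lay within 500 bp of an annotated start site, a class that took 13.6% ± 0.55 (SD of 1000 sets) of random positions on the same arms. Introns held 378 summits (8.96%, against 39.4% of random positions), intergenic sequence 203 (4.81%, against 27.3%), and coding exons 43 (1.02%, against 13.7%). The remaining summits were 25 in 3' UTRs, 16 in 5' UTRs and 13 in noncoding exons, each class below its random share. Promoter, coding exon, 3' UTR, noncoding exon, intron and intergenic shares all lay outside the 1000 random sets (permutation p = 0.002, two-sided, the smallest they can give), and the 5' UTR share had p = 0.004. Promoter summits lay close to the start site itself, with a median of 28 bp upstream and quartiles of 99 bp upstream and 47 bp downstream of the nearest coding start site, and 63.0% of them were upstream. They belonged to the start sites of 2958 genes. Promoter peaks were also the stronger ones, with a median signal of 116 against 88.2 for the 678 other peaks (difference 27.8, permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give).

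**Figure D1:**
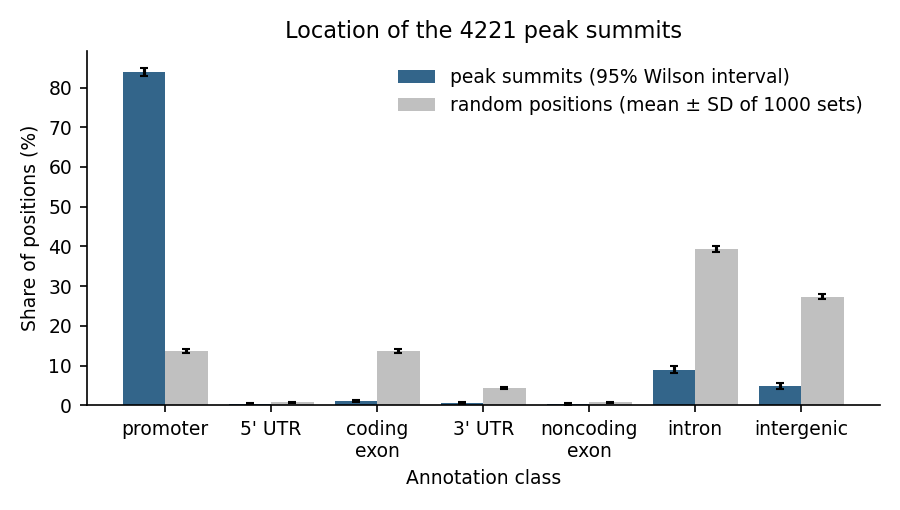
Share of the 4221 peak summits (blue, with 95% Wilson intervals) and of random positions on the same arms (grey, mean and SD of 1000 sets) in each annotation class, in percent. Promoters, within 500 bp of a start site, hold 83.9% of summits and 13.6% of random positions.

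**Figure D2:**
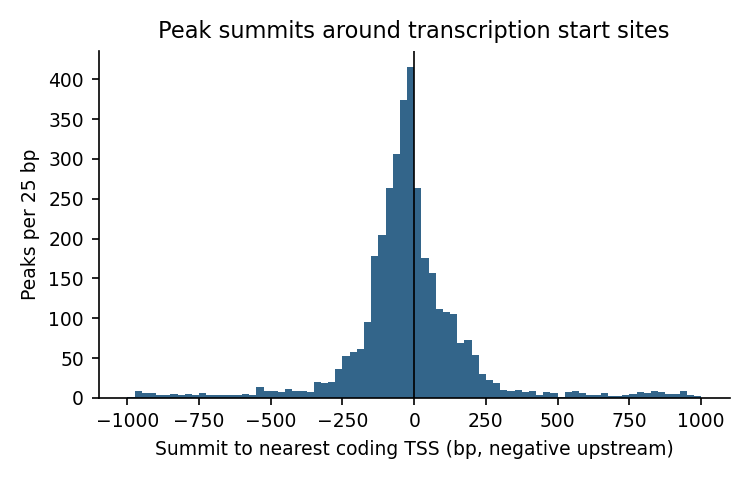
Number of peaks per 25 bp against the distance of the summit from the nearest coding start site in bp, with negative values upstream, for peaks within 1000 bp. Summits gather just upstream of the start site, with a median of 28 bp upstream among promoter peaks.

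The strongest peaks lay at promoters. The first was at RhoGAP93B on 3R from 21097720 to 21098133, with a signal of 1152 and its summit 95 bp upstream of the start site. Next came Rpn6, a proteasome subunit, on 2R from 14752158 to 14752648 (signal 1111, 95 bp upstream), and mtSSB, the mitochondrial single-stranded DNA-binding protein, on 3R from 16205060 to 16205514 (signal 1106, 40 bp upstream). The peak at the ribosomal protein gene RpL32 covered 3R from 30046059 to 30046513 with a signal of 889 and lay 98 bp upstream. Gp150 followed on 2R from 22317322 to 22317733 (signal 861, 129 bp upstream), then Mic26-27 on 3R from 16146502 to 16147118 (signal 847, 25 bp upstream). Creld on 2L from 102177 to 102601 had a signal of 828 with its summit 1 bp downstream. MESK2 on 2R from 21501695 to 21502173 reached 812, Jwa on 2L from 18705615 to 18706005 reached 757, and Hacl on 2R from 20245305 to 20245721 reached 737, with summits 126, 115 and 100 bp upstream. The next 5 peaks, at Sry-alpha, Capr, Ube3a, hts and CG1965, had signals from 730 to 690 and were promoter peaks too. Each of these 15 peaks overlapped a peak in both replicates' own lists. All but the one at CG1965 held the sequence CGATA within 100 bp of the summit, and none held CAGGTG.

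Genes known for their part in Snail biology had peaks of ordinary strength. Of 17 such genes fixed beforehand, 15 had a summit within 5000 bp of the gene, 8 of them with a strongest peak above the list's median signal of 109 and none among its strongest 10%. Of all coding genes 52.7% had such a summit, and no test matched on gene length was run for these 17. The strongest peak of a gene is here set against all single peaks, which favours genes with several. The sna gene itself had 1 peak, at its promoter on 2L from 15478151 to 15478666 (signal 99.9, summit 149 bp upstream), which overlapped a peak of replicate 2 only. Its paralogs escargot (esg) and worniu (wor), which act with it in neuroblasts, had promoter peaks of 178 (2L from 15333481 to 15333996) and 86.5 (2L from 15425708 to 15426223). Among genes that Snail is known to repress in the mesoderm, the strongest peak of rho was at its promoter (3L from 1463482 to 1463997, signal 111), as were those of sog (X from 15633230 to 15633745, signal 98.1) and brk (X from 7307347 to 7307862, signal 110). The midline gene sim had 2 peaks, the stronger in an intron (3R from 13064168 to 13064683, signal 113). The ths and vnd genes had no peak in the main list, although 52 and 16 candidate regions, with signals up to 57.7 and 45.5, lay in their spans. The embryos were whole and aged 0 to 24 h, and the share of cells with the fusion protein was not measured. A weak or missing peak therefore does not show that binding was absent in some cells or stages.

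Among mesodermal genes, Mef2 had 3 peaks, the strongest at a promoter (2R from 9958406 to 9958921, signal 118), and the promoters of the FGF receptor gene htl (signal 79.1), of zfh1 (79.6) and of fog (92.1), whose product starts apical constriction, also had a peak. The E-cadherin gene shotgun (shg), a classical target of Snail-family repression, had its stronger peak at its promoter (2R from 21057153 to 21057433, signal 244, 96 bp upstream). The strongest peaks counted to 3 further genes were nearest to the start site of a neighbour: that of tin (signal 245) to mod(mdg4), that of twi (38.8) to CG9896, and that of the mitotic activator stg (277) to SP1029. The strongest peak overlapped a peak in both replicates' own lists for 5 of the 15 genes (esg, Mef2, tin, shg and stg), in 1 replicate for 4 (sna, rho, sog and brk) and in neither for 6 (wor, twi, sim, htl, zfh1 and fog).

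Counted by gene, with no adjustment for gene length, the most summits within 5000 bp lay at sbb and EcR. There were 12 summits at sbb, 10 at the ecdysone receptor gene EcR, and 9 each at CG1677, the ecdysone-induced gene Eip74EF, SNF4Agamma, the nuclear receptor gene ftz-f1 and the Notch coactivator gene mam. The genes CG5554, jvl and msn had 8 each. Only at ftz-f1 (signal 195), mam (265) and jvl (534) was the strongest of these summits nearest to the gene's own start site.

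Gene lists fixed before the data were examined asked which gene groups carried peaks more or less often than random coding genes of the same length. Of 13945 coding genes, 7353 (52.7%) had a summit within 5000 bp. Genes for ribosomal proteins and for epithelial polarity and adhesion had peaks more often than random lists, and chemoreceptor genes less often. These 3 of 20 lists passed a permutation test against 10000 length-matched random lists (two-sided, Benjamini-Hochberg over the 20 lists). A peak so counted can belong to a neighbour: of the 72 list members named here with their strongest peak, 48 had it nearest to the start site of another gene. Of 92 ribosomal protein genes 67 had a peak against 42.8 by chance (adjusted permutation p = 0.002), led by RpL32 (889), RpLP1 (584), RpS13 (545) and RpS7 (526). These genes were taken by symbol and include some with a symbol ending in -like, whose products were not checked to be ribosomal proteins. The peaks of RpLP1 and RpS13 were nearest to the start sites of CG11885 and Pp2A-29B. Counting a peak to its nearest start site only, 36 ribosomal protein genes had one against 15.5 by chance (adjusted permutation p = 0.002), whereas within the gene spans alone the excess was lost, with 9 genes against 7.30 (adjusted permutation p = 1). Of 18 polarity and adhesion genes 17 had a peak against 10.9 (adjusted permutation p = 0.025), with Nrg (678), crb (265), dlg1 (259) and shg (244) the strongest and kune without one. The peaks of crb and dlg1 were nearest to the start sites of Uck and hop. This call was lost with each replicate's own list, at 11 genes against 7.62 for replicate 2 (adjusted permutation p = 0.43) and 14 against 8.99 for replicate 1 (adjusted permutation p = 0.086), and with the peaks above the median signal, at 11 against 7.72 (adjusted permutation p = 0.46). The call was also lost with peaks counted to the nearest start site only, at 12 against 6.41 (adjusted permutation p = 0.064), and within gene spans alone, at 10 against 5.06 (adjusted permutation p = 0.15). In each of these settings the count stayed above that of random lists. Of 179 chemoreceptor genes, which act in sensory neurons, 40 had a peak against 94.3 (adjusted permutation p = 0.002), the strongest being those of Gr59f (614), Ir51b (527), Ir85a (437) and Ir60d (346). All 4 of these were nearest to the start site of another gene, and 2 chemoreceptor genes were the nearest to any peak.

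The lists of neuroectodermal, mesodermal, neuroblast, dorsal ectoderm, Notch target, early zygotic and cell cycle genes did not pass the test. Of 20 neuroectodermal genes that Snail represses in the mesoderm 12 had a peak against 11.0 (adjusted permutation p = 0.92), with crb (265), shg (244) and the shared peak of E(spl)m7-HLH and E(spl)m8-HLH (216, nearest to gro) the strongest. With peaks counted to the nearest start site only, the excess was larger and again did not pass, at 10 genes against 5.38 (adjusted permutation p = 0.18). Of 26 genes of mesoderm and gastrulation 18 had one against 15.4 (adjusted permutation p = 0.64), led by stg (277), PolE4 (273), tin (245) and if (196), of which only PolE4 was nearest to its own peak. For 21 neuroblast genes the count was 15 against 12.5 (adjusted permutation p = 0.64), with brat (309), stg, pros (261) and pon (218) first and only brat nearest to its own. The dorsal ectoderm and BMP list had 14 of 19 genes with a peak against 11.3 (adjusted permutation p = 0.64), led by Ance (333), tld (291), Mad (196) and tkv (169), of which only tkv was nearest to its own peak. By nearest start site the counts were 12 against 8.35 for mesoderm (adjusted permutation p = 0.33), 10 against 6.55 for neuroblasts (adjusted permutation p = 0.33) and 10 against 5.93 for dorsal ectoderm (adjusted permutation p = 0.26). Of 11 Notch target genes of the Enhancer of split complex 4 had one against 4.42 (adjusted permutation p = 1), namely the pair above and E(spl)malpha-BFM and E(spl)mbeta-HLH, which share a peak of 102. Early zygotic genes had a peak in 6 of 18 cases against 9.26 (adjusted permutation p = 0.47), with Sry-alpha (889, the RpL32 peak), CG9775 (311), sisA (119) and zld (81.4) the strongest and only zld nearest to its own. Of 17 cell cycle genes 13 had one against 10.3 (adjusted permutation p = 0.64), led by twe (427), Rbf (397), fzy (353) and CycB (349), of which only CycB was nearest to its own peak.

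The lists of segmentation, muscle structural and neuronal genes lay below chance without passing the adjusted test in the main list. Of 23 segmentation genes 8 had a peak against 13.7 (adjusted permutation p = 0.12), led by bcd (166), wg (134), knrl (123.5) and gsb-n (123.2). Muscle structural genes had 7 of 20 against 12.2 (adjusted permutation p = 0.12), with Zasp52 (116), sls (96.0), Tm1 (93.1, nearest to MRG15) and Mlp84B (84.6, nearest to Alh) first. Neuronal genes had 6 of 17 against 10.6 (adjusted permutation p = 0.14), with Syt1 (223), nSyb (151), cpx (78.2) and futsch (75.3) first, all 4 of them peaks nearest to another gene. All 3 passed it in each replicate's own list and among the peaks above the median signal. With the replicate-pair list only the neuronal genes did, at 3 against 10.04 (adjusted permutation p = 0.011), and segmentation and muscle genes did not (adjusted permutation p = 0.071 for both). In replicate 2, 1 segmentation gene had a peak against 9.63 (adjusted permutation p = 0.0013), 1 muscle gene against 8.55 (adjusted permutation p = 0.003) and 2 neuronal genes against 7.42 (adjusted permutation p = 0.048). In replicate 1 the counts were 5 against 11.8 (adjusted permutation p = 0.031), 3 against 10.2 (adjusted permutation p = 0.0067) and 3 against 8.72 (adjusted permutation p = 0.048). With peaks counted to the nearest start site only, the segmentation deficit was lost, with 7 genes against 6.57 (adjusted permutation p = 1), and muscle (3 against 6.40, adjusted permutation p = 0.33) and neuronal genes (2 against 6.38, adjusted permutation p = 0.18) stayed below chance without passing.

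The other marker lists did not pass the test in the main list. Glial genes had a peak in 8 of 11 cases against 6.85 (adjusted permutation p = 0.91), led by loco (428), wrapper (231, nearest to Rtf1), moody (218, nearest to usp) and pnt (142). Blood cell and fat body genes had 7 of 15 against 9.28 (adjusted permutation p = 0.64), with Lsp2 (320), vkg (215), srp (166) and Pxn (129), all 4 of them peaks nearest to another gene. Midgut genes had 7 of 14 against 7.54 (adjusted permutation p = 1), with Jon65Aiii (298, nearest to tant), esg (178), GATAe (166) and dve (161). Tracheal genes had 11 of 16 against 10.01 (adjusted permutation p = 0.92), with btl (256), pio (221, nearest to CG3548), esg and pnt. Germline genes had 9 of 12 against 7.42 (adjusted permutation p = 0.81), with the strongest peaks counted to bgcn (677), nanos (454), piwi (404) and bam (284), which were nearest to the start sites of Pym, CG11779, TTLL4A and Nup358. Hox genes had 4 of 8 against 4.94 (adjusted permutation p = 0.91), with Ubx (176, nearest to CG14907), Antp (161), Abd-B (133) and abd-A (93.4). Genes taken by symbol as late serine proteases had 10 of 26 against 11.5 (adjusted permutation p = 0.91). Of these, 3 (SerRS, SerRS-m and SerT) are not proteases, and without them, a change made after the data were seen, the count was 8 of 23 against 9.73 (adjusted permutation p = 0.86), with 1 shared peak of Jon65Ai, Jon65Aii and Jon65Aiii (298, nearest to tant) and that of Phae1 (186, nearest to Rab6) the strongest.

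**Figure D3:**
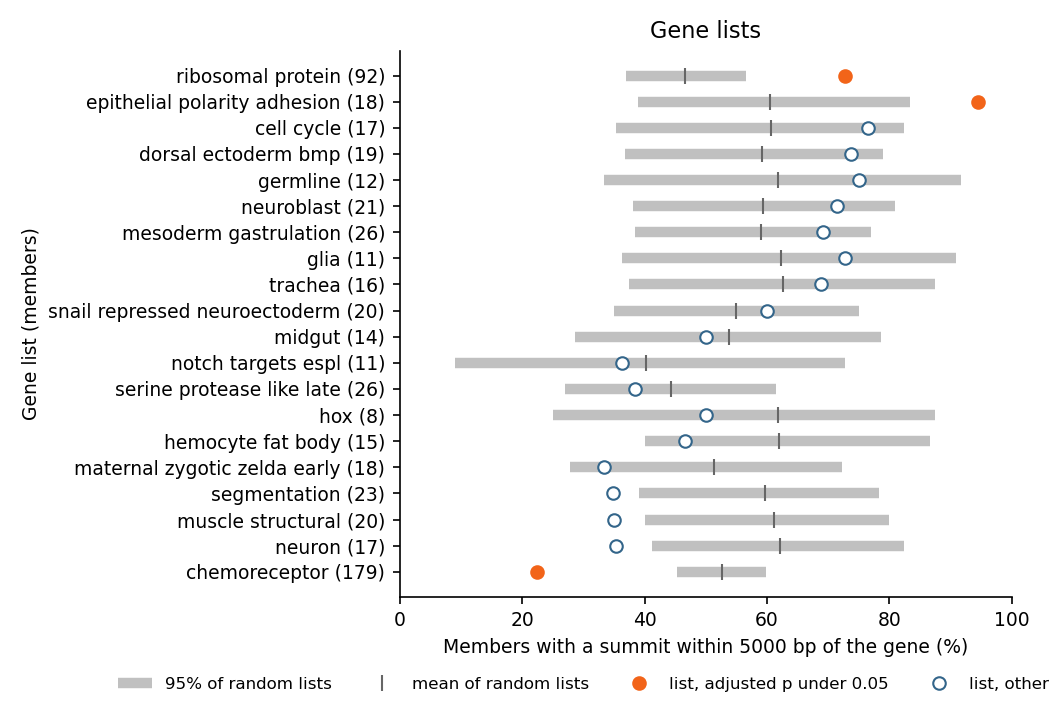
Percentage of the members of each of 20 gene lists with a summit within 5000 bp of the gene (circles, filled where the adjusted p is under 0.05), with the mean (ticks) and the central 95% (grey bars) of 10000 length-matched random lists. Ribosomal protein and polarity genes lie above their bars and chemoreceptor genes below.

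The sequence preferred by Snail-family proteins, the E-box CAGGTG, was less common at the summits than beside them. It occurred within 100 bp of 6.44% of the summits (95% Wilson interval 5.74 to 7.23) and in 10.1% (9.27 to 11.1) of windows of the same width 1000 bp away, a ratio of 0.64 (exact McNemar test, adjusted p = 2.24e-09 over 17 motifs). TATCGATA, the DNA replication-related element of housekeeping promoters, occurred at 17.7% of summits and 0.545% of flanks, a ratio of 32.4 (adjusted exact p = 9.64e-189). Core promoter motif 1, GGTCACACT, occurred at 3.96% against 0.213% (adjusted exact p = 6.80e-38), the GAGA factor repeat GAGAGAG at 9.36% against 3.63% (adjusted exact p = 3.50e-27) and the E-box CAGCTG at 16.7% against 11.1% (adjusted exact p = 3.79e-13). Set promoter against promoter, however, GAGAGAG was not commoner with a peak: 3.485% of coding promoters with a peak held it and 4.48% without. In the distal peaks alone GGTCACACT (ratio 1.67, adjusted exact p = 0.82) and CAGCTG (0.948, adjusted exact p = 0.85) did not pass. With the list of replicate 2 all 4 stayed higher, with ratios of 58.9 for TATCGATA, 11.6 in place of 18.6 for GGTCACACT and 1.71 in place of 2.58 for GAGAGAG. Besides CAGGTG, 3 other motifs were lower at summits: CATCTG (6.75% against 10.8%), CACATG (7.87% against 10.4%) and the Zelda site CAGGTAG (0.924% against 1.78%). The call for CAGGTAG was lost with each replicate's own list (ratio 0.66, adjusted exact p = 0.20 for replicate 2; 0.60 and 0.12 for replicate 1), with the nearer and the farther flanks (0.70 and 0.17; 0.64 and 0.060) and against matched candidates (0.78 and 0.35), where the main ratio was 0.52. That for CACATG, with a main ratio of 0.76, was lost in windows of 50 bp (ratio 0.80, adjusted exact p = 0.055) and with both of those flanks (0.88 and 0.17; 0.90 and 0.22). The other 9 of the 17 motifs did not pass the adjusted test.

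In a scan of all strand-collapsed 6-mers, 417 were higher and 696 lower at the summits after adjustment. The first were TATCGA (39.4% of summits, 7.56% of flanks), CGATAG (31.9% and 4.62%) and ATCGAT (34.7% and 6.42%), and 10 of the 20 strongest held CGATA or ATCGA. Others of the 20 were made of A and T only, such as AAAATA (42.3% and 27.65%). Those lower at summits included GGAGGA (5.31% and 13.2%). Base composition was not matched between summits and flanks, so its part in the lower share of CAGGTG was not tested. CAGGTG ranked 1959 by the difference in share. Against candidates matched on location class its share was 6.44% against 9.95% (Fisher's exact test, adjusted p = 1.65e-08). Of coding promoters with a peak 5.05% held CAGGTG near the median summit position, and of those without a peak 6.87%, a smaller difference that was not tested. In the 678 distal peaks CAGGTG occurred at 7.08% of summits and 7.08% of flanks (adjusted exact p = 1). Whether promoter and distal peaks differ in this was not tested.

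**Figure D4:**
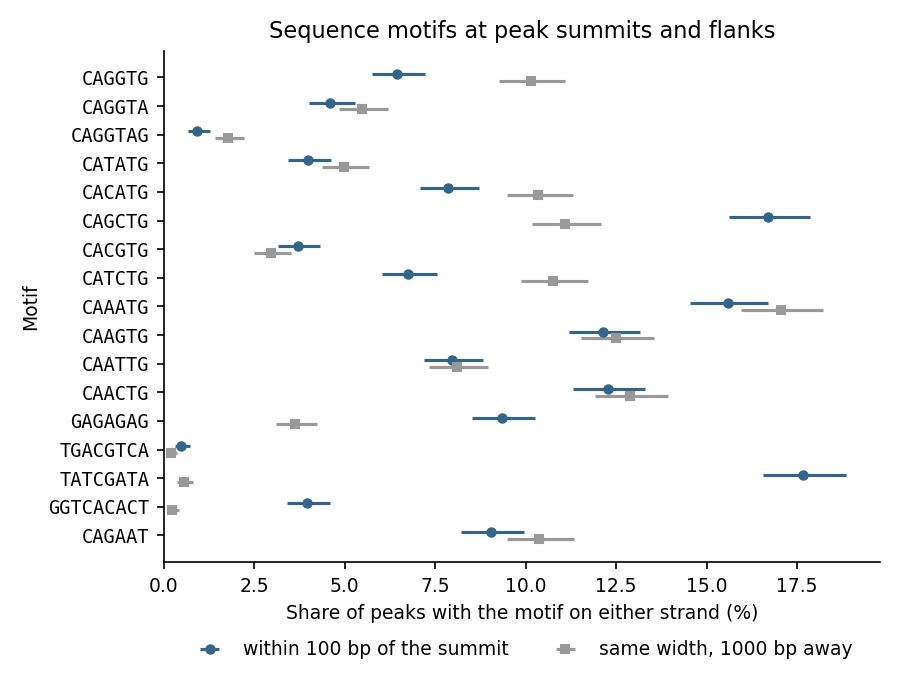
Percentage of the 4221 peaks with each of 17 motifs on either strand within 100 bp of the summit (blue circles) and in a window of the same width 1000 bp away (grey squares), with 95% Wilson intervals. TATCGATA stands at 17.7% against 0.545%, and CAGGTG at 6.44% against 10.1%.

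Stronger peaks held the E-box CAGGTG less often and TATCGATA more often. From the weakest to the strongest of 5 signal quintiles the share with CAGGTG was 9.47%, 6.99%, 6.40%, 5.09% and 4.27%, and the correlation of signal rank with its presence was -0.070 (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give). The share with TATCGATA was 3.67% in the weakest quintile and 38.4% in the strongest (correlation 0.33, permutation p = 1e-05). GAGAGAG went from 10.2% in the weakest quintile to 13.7% in the middle one and 2.25% in the strongest (correlation -0.10, permutation p = 1e-05). The promoter share was 77.6% in the weakest quintile, 72.0% in the next and 96.9% in the strongest. Promoter peaks alone, merged where they overlapped (3008 sites), were examined after seeing the data. From their weakest to their strongest quintile CAGGTG fell from 8.804% to 3.827% (correlation -0.074, permutation p = 3e-05). TATCGATA rose from 5.814% to 37.77% (0.29, permutation p = 1e-05), and GAGAGAG fell from 10.96% to 1.498% (-0.14, permutation p = 1e-05). These values argue against promoter share as the only source of the 3 trends. Among the peaks above the median signal alone the correlation for CAGGTG was -0.029 (permutation p = 0.18).

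**Figure D5:**
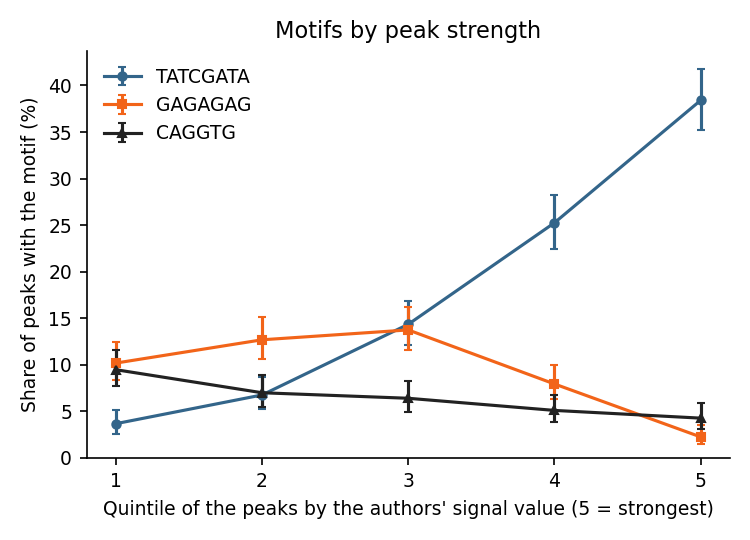
Percentage of peaks with TATCGATA, GAGAGAG or CAGGTG within 100 bp of the summit in each signal quintile of the 4221 peaks (5 is the strongest), with 95% Wilson intervals. TATCGATA runs from 3.67% to 38.4% and CAGGTG from 9.47% to 4.27%.

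Peaks were spread over the large arms in near proportion to their length, with more on 2R and fewer on the small chromosome 4. Arm 2R had 923 peaks, 1.16 times the number its length gives (exact binomial test, adjusted p = 7.07e-06 over 6 arms), and chromosome 4 had 17, 0.40 times that number (adjusted exact p = 4.14e-05). Among the peaks above the median signal the excess on 2R no longer passed (1.10, adjusted exact p = 0.060), and 3L lay below its share there (0.90, adjusted exact p = 0.048) and in the replicate 2 list (0.90, adjusted exact p = 0.033). The X had 714 peaks, 30.3 per Mb, at 0.96 times its share (adjusted exact p = 0.39). Set against the number of coding genes, the ratios were 1.07 for 2R (adjusted exact p = 0.070) and 0.70 for chromosome 4 (adjusted exact p = 0.18), so neither arm then passed the test. Against the candidate regions of each arm chromosome 4 had 1.34 times its share (adjusted exact p = 0.31), whereas 2R stayed above its share (1.15, adjusted exact p = 1.32e-05) and the X (0.90, adjusted exact p = 0.0035) and 3R (0.93, adjusted exact p = 0.028) lay below theirs.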

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

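Some regions at the IDR limit were not used in the comparisons. In the pooled candidate list 4366 regions reached the limit of 0.01, and 144 of them are not among the 4222 thresholded peaks. Their median signal was 106 against 109 for the regions that are. The other 3 pairs of lists differ in the same way, by 146 regions for the replicate pair, 95 for replicate 1 and 92 for replicate 2. The reason is not given in the sources used here, and a filter of the authors was not tested. These regions were not analysed here.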

How the results depend on the processing

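The lists of each replicate alone, the replicate-pair list, the other overlap rules, promoter widths, windows, flanks and backgrounds were planned. Merging overlapping peaks, splitting promoter from distal peaks and leaving 3 genes out of the protease list (ratio 0.822) were chosen after seeing the data. Under every setting run for them, the promoter share stayed above its background (73.5% to 92.2%), replicate overlap above the shuffles (47.98% to 82.0% of replicate 1 peaks, 61.9% to 82.4% of replicate 2 peaks) and promoter peaks stronger than distal ones (difference 16.2 to 45.8). CAGGTG lay below its background in every setting except distal peaks only, where the ratio was 1, with 2 motifs higher, 0 lower, CACATG at 1.18 and CAGCTG at 0.948; that set holds 678 of the 4221 peaks. The ratio of TATCGATA ran from 13 in distal peaks and 14.6 against matched candidates to 58.9 in replicate 2, that of GGTCACACT from 1.67 in distal peaks, where its call was lost, and 3.98 against matched candidates to 52 above the median signal, and that of GAGAGAG from 1.71 in replicate 2 to 4.65 with the farther flanks. The correlation of CAGGTG with signal missed the threshold among the peaks above the median signal (-0.029), and the cause was not tested. Depth is unknown, so its effect on the lengths of the lists could not be assessed.

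The number of gene lists past the threshold was 5 in place of 3 in each replicate's own list (5 to 5) and above the median signal, 4 with the replicate-pair list, 2 by nearest start site and 1 within gene spans alone. The number of arms was 0 against coding genes and 3 both against candidate regions, where the X (0.897) and 3R (0.935) newly passed, and in replicate 2, where 3L did (0.901); above the median signal 2R (1.10) no longer passed and 3L (0.898) did. The X ratio turned to 1.02 above the median signal and 1.07 against coding genes, and chromosome 4 to 1.34 against candidate regions. No list that passed in the main list changed direction. Among those that did not pass there, ratios changed side with the replicate-pair list (Snail-repressed 0.867, dorsal ectoderm 0.937, Hox 1.28, midgut 1.12, trachea 0.947), above the median signal (mesoderm 0.9996, neuroblast 0.777, dorsal ectoderm 0.855, glia 0.795, trachea 0.823), within spans (Hox 1.61, glia 0.813), within 2000 bp (glia 0.885), within 10000 bp (Snail-repressed 0.918, Notch targets 1.39, proteases 1.02), by nearest start site (segmentation 1.06, Hox 1.32, midgut 1.41) and matched on candidates (proteases 1.01). With each replicate alone they ranged from 0.652 to 1.08 (Snail-repressed), 0.860 to 1.12 (mesoderm), 0.762 to 1.37 (neuroblast), 0.890 to 1.06 (dorsal ectoderm), 0.870 to 1.23 (Hox), 0.937 to 1.14 (midgut) and 0.852 to 0.948 (trachea). The cause was not tested for these, and none passed the threshold. Values that changed side are given for 2R, chromosome 4, the X and the motifs that passed; this choice was made after the values were seen, and sign changes of other arms and motifs (such as 3R, 1.01 with the replicate-pair list and 1.02 in replicate 2), none of them past the threshold in the main list, are left out. Of the motifs that did not pass in the main list, CATATG, CAAATG, CAGGTA, CACGTG, CAACTG, TGACGTCA and CAGAAT each passed in at least 1 other setting. Of the other values of single lists, of 2R, chromosome 4 and the X and of the motifs that passed, 11 newly passed it and 20 no longer passed, with the same direction.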

Other observations

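The gene families in this paragraph and the next were chosen after the peaks were seen. Of 5 families with general cellular roles, 3 carried peaks more often than length-matched random genes: 58 of 73 mitochondrial ribosomal protein genes had a summit within 5000 bp against 29.7 by chance (permutation test, adjusted p = 0.00053 over 8 families), as did 27 of 32 aminoacyl-tRNA synthetase genes against 18.9 (adjusted permutation p = 0.0084) and 19 of 25 Mediator subunit genes against 12.7 (adjusted permutation p = 0.023). Proteasome genes had 30 of 48 against 23.3 (adjusted permutation p = 0.090) and translation initiation factors 27 of 44 against 24.2 (adjusted permutation p = 0.47). With peaks counted to the nearest start site only, mitochondrial ribosomal protein genes (27 against 9.81, adjusted permutation p = 0.00053) and proteasome genes (16 against 8.60, adjusted permutation p = 0.021) passed, and the synthetase and Mediator genes did not (adjusted permutation p = 0.48 for both).

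Cytochrome P450 genes had 26 of 85 against 48.6 (adjusted permutation p = 0.00053) and cuticular protein genes 8 of 70 against 31.8 (adjusted permutation p = 0.00053), and none of the cuticular genes (0 against 12.2) was nearest to a peak. Odorant-binding protein genes had 14 of 51 against 20.2 (adjusted permutation p = 0.11), and 1 against 6.75 by nearest start site (adjusted permutation p = 0.021). Coding genes with the start site of another gene within 500 bp upstream on the other strand had a promoter peak in 51.7% of 3686 cases, against 16.4% of the other 10259 (difference 35.3 percentage points, 95% Newcombe interval 33.5 to 37.0), though the window around such a gene holds a pair of promoters. At the 600 merged distal sites the 6-mers that led were of the GAGA type, with AGAGCG at 30.3% of summits against 8.67% of flanks and GAGAGA at 29.8% against 10.8%.

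The first test of TATCGATA and the comparison of E-boxes below were chosen after the result was seen, and the other tests before. The pattern is that TATCGATA is commoner at the summits than beside them and CAGGTG is not. TATCGATA was held by 17.7% of the summits only. Of the 3587 promoters with a peak, 2355 held none of TATCGATA, GGTCACACT and GAGAGAG in the window used below. A composition shared by all promoters was argued against. In a window at the same place, 24.5% of 3587 promoters with a peak held TATCGATA and 2.43% of 10358 without one. The difference was 22.0 percentage points (95% interval 20.6 to 23.5). The GC content of these windows was 39.6% and 41.2%. It was not matched, and the peaks are those in which the pattern was seen. Of 1130 promoters with TATCGATA 77.7% had a peak, against 36.3% of 678 with GGTCACACT and no TATCGATA. These shares lay 41.4 percentage points apart (95% interval 37.0 to 45.7). Equal shares, which were predicted beforehand for signal at active promoters of any class, are thus argued against. Promoter activity was not measured, so signal that varies with activity stays open. Of all promoters 25.7% had a peak, and of those with none of TATCGATA, GGTCACACT and GAGAGAG 20.3%. Of 561 promoters with GAGAGAG and neither of the other 2 motifs, 19.25% had a peak. GAGAGAG was held by 3.485% of promoters with a peak and 4.48% of those without, a difference that was not tested. A mislabelled line or another tagged protein stays open, because the block of raised candidate signal at sna, 5000 bp long, was neither absent nor as long as the 20000 bp set beforehand, and the raised signal around it, given below, has open causes of its own; no biological explanation was tested, since the design has 1 group.

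Candidate regions around the sna gene had a raised signal, noticed in the data before it was tested: within 20000 bp the median of 29 candidates was 34.7 against 20.1 in the median random window of arm 2L, as high as the highest 1.22% of 980 windows, whereas the windows at esg (15.9) and wor (21.6) lay at percentiles 14.5 and 61.7. Promoter-rich surroundings were argued against, since without promoter candidates the value lay at percentile 99.2. Extra copies of the locus on the transgene would raise a long block, and the contiguous block of 5000 bp bins at or over the 95th percentile was 5000 bp long (95% bootstrap interval 5000 to 10000, added after the length was seen), which the limit of 10000 bp set beforehand counts against them. Of the 9 bins within 20000 bp, however, 2 more to the right were over the limit of 44.7 (68.3 and 50.3), 2 between were under it (40.7 and 34.7) and 2 to the left held no candidate, so the raised bins span 25000 bp and extra copies stay open. Binding by the fusion protein at its own locus was not tested and stays open too, as does chance, and no control sample was used here.

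CAGGTG was raised at the weak distal candidates that are not in the thresholded list, which was also noticed before it was tested. At 43631 such sites it occurred at 10.3% of summits against 8.41% of flanks, a ratio of 1.23 (95% interval 1.18 to 1.28). This is consistent with base composition, since 80.0% of the 120 6-mers made of the same bases had a lower ratio, short of the top 5% that would have argued against it. It is also in line with E-boxes in general, as CAGGTG came second, at rank 2 of 10 CANNTG sequences, after CAGCTG (ratio 1.27). Specific recognition of CAGGTG at these sites therefore may or may not be present, and these tests leave it open.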
